A study of Mus musculus with 6 samples.

How the data were processed

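Total RNA from 6 whole mouse livers was hybridised to Illumina BeadChip arrays, 3 from mice given Ad-MafG and 3 from mice given Ad-Control. Per the labels' protocols, RNA was extracted with QIAzol and an RNeasy kit, checked on a Bioanalyser and amplified into biotin-labelled cRNA with a TotalPrep kit. Groups and replicate numbers were taken from the sample labels, and per the series' design text each sample is a separate mouse. All 6 arrays lay on 1 slide, so no slide term was fitted.

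The deposited files hold 3 tables. The first gives, per the file headers, the non-normalized mean bead intensity of each probe on each array and a detection p-value. That p-value is the chance that background alone gives a signal at least that high. The second holds intensity values that the authors had background-subtracted and scaled; set against the first table, each array's column was a straight line of its non-normalized signal, with scale factors from 0.872 to 1.195. These values are linear and uncentred, 1272 to 6904 of them per array are negative, and their median per array was between 34.2 and 46.0. Each column follows its own array, so its direction is known, but the scaling method is not given in the sources used here. The third is the authors' deposited table of group means of those scaled intensities, with a detection p-value for each mean, the number of arrays, and a signed difference score of Ad-MafG against Ad-Control, per the file headers. The error model behind that score is not given in the sources used here. The authors' group means differed from the mean of the 3 scaled values per array by at most 0.057. The scanner software and its version are not given in the sources used here.

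Values were computed from the non-normalized table with limma 3.58.1 in R 4.3.3. Background was removed by normexp with its parameters inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and taken to log2 (the neqc recipe). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 12893 of 25697. Genes were named from the platform annotation, in which 23978 probes had 1 gene symbol, 0 had several and 1719 had none. The Entrez gene number of 23962 probes was found in the RefSeq gene table of GRCm38.p6, and 0 symbols changed through it. No coordinates are given because the array files name no genome build. For each gene the probe with the highest mean over all 6 arrays stood for it, which left 8827 genes; 2361 of them had further probes past the filter. Of the 875 changed genes 229 had further probes, 318 in all, and 14 of these had the opposite sign, 0 of them past the threshold. Of those described in the text Gstm6 had such a probe. Probes without a gene were kept out of all gene counts.

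Groups were compared with lmFit and eBayes, without covariates, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A gene whose probes were not above background (detection p of 0.05 or more) on all 3 arrays of a group has only a bound there. Its fold is the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own, and is written as "at least"; 62 changed genes had such a group. Gene lists and cell type markers were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over all 31 lists; camera with an estimated correlation and fry's directional test were the alternatives. Lists covered bile acid synthesis, bile acid and bile lipid transport, nuclear receptors and regulators of bile acid metabolism, partners and relatives of MafG (the CNC, BACH and Maf families), NRF2 targets, heme and iron, cholesterol synthesis, fatty acid synthesis and oxidation, gluconeogenesis and glycogen, xenobiotic cytochromes P450, hepatocyte secretory genes, male-biased and female-biased genes, type I interferon and interferon gamma responses, acute phase, unfolded protein response, p53 targets, cell cycle, immediate early and heat shock genes, and the circadian clock. Markers covered hepatocytes, T and NK cells, B and plasma cells, Kupffer cells and macrophages, neutrophils, sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes and erythroid cells. The list of MafG partners and relatives also held Keap1, which is not of the CNC, BACH or Maf families. Of the listed genes tested, 6 stand in more than 1 list.

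The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named were Mafg; the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose groups did not overlap, leaving out symbols without a gene name of their own; up to 4 tested members of each list with the smallest unadjusted p; and every tested member of the lists of bile acid synthesis and of transport. This gave 154 genes, of which 67 passed the threshold.

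Alternatives were no background correction, an offset of 50, median scaling or cyclic loess in place of quantile normalization, the authors' scaled values (floored at 16 before log2), no detection filter, a detection p under 0.01 on all 6 arrays, the mean of a gene's probes, every probe on its own, eBayes with trend and robust, array weights, the replicate number as a block, and each array left out in turn. The limma fit and its threshold were tested on simulated data with 200 changed genes among the 8827 in each of 10 runs, for Ad-MafG against Ad-Control. Noise was drawn around the normalized gene means with the SDs that eBayes had moderated. Background correction, normalization, the detection filter and the choice of probe were therefore not tested. The fit recovered 40.3% of 1.5-fold, 89.9% of 2-fold and 99.8% of 4-fold changes, with 5.44% of its calls false. These rates hold for that noise and need not hold for the data. The list test was first simulated in 20 runs, in which it called 20 of 20 lists of 16 genes shifted by 0.5 and 3 of 20 unshifted lists at an unadjusted threshold of 0.05. Since 3 of 20 was more than that threshold allows on average, the runs were extended to 100, which called 100 shifted and 4 unshifted lists. In all these simulations genes varied independently of each other, so they do not test the preset correlation of 0.01. In the data the estimated correlation ran from -0.417 for cholangiocyte markers to 0.67 for male-biased genes, with 0.488 for NRF2 targets.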

Results

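Gene expression was measured in the whole liver of 6 wild-type C57BL/6 mice with Illumina BeadChip arrays, on which each probe reports the brightness of labelled RNA bound to beads. In 3 mice the treatment was Ad-MafG and in the other 3 it was Ad-Control, named Ad-CMV in the labels. Livers were taken after 5 days and a fast of 4 to 6 h, and each array stands for a separate mouse. MafG is a small Maf protein, a transcription factor that binds DNA as a dimer with partners such as NRF2 or BACH1, and the series title names its overexpression. The median signal per array lay between 160.6 and 180 in the Ad-Control group and between 181.6 and 185.8 in the Ad-MafG group. Between 12079 and 13042 of the 25697 probes were detected on each array. Across genes, normalized values correlated at 0.984 to 0.989 between Ad-Control arrays, 0.989 to 0.993 between Ad-MafG arrays and 0.958 to 0.983 between the groups. Genes are not independent replicates in these correlations, and the number of arrays limits the precision of every value below. All fold changes are Ad-MafG over Ad-Control on the log2 scale of normalized intensity, with limma's Benjamini-Hochberg adjusted p.

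The array's only Mafg probe gave a lower signal in the livers labelled Ad-MafG. Its normalized log2 intensity was 10.86 ± 0.16 (SD, n = 3) in Ad-Control and 10.32 ± 0.06 (SD, n = 3) in Ad-MafG. The log2 fold change was -0.54 with an SE of 0.11 and an adjusted p of 0.0341, and all 3 Ad-MafG livers lay below all 3 Ad-Control livers. The authors' deposited table gives a mean intensity of 1814.5 for Ad-Control and 1250.5 for Ad-MafG, with a difference score of -33.6. Where the probe's target lies in Mafg, and whether the Ad-MafG insert contains it, is not given in the sources used here. The probe therefore does not check the group labels, and every direction below rests on those labels. The adjusted p of Mafg was 0.0796 without Ad-Control 1, 0.0884 without Ad-Control 3, 0.0861 without Ad-MafG 1, 0.0864 without Ad-MafG 2 and 0.109 without Ad-MafG 3.

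In the livers labelled Ad-MafG, 555 genes were higher and 320 lower than in Ad-Control, together 875 of 8827 genes tested. The most strongly raised gene was Cbr3, a carbonyl reductase, which rose 35.0-fold from 7.33 ± 0.73 to 12.46 ± 0.78 (SD, n = 3 each). Spink1, a trypsin inhibitor, rose 24.1-fold, with a log2 fold change of 4.59 and an SE of 0.46, and was detected on 2 of the 3 Ad-Control arrays. The glutathione transferase gene Gstm3 was at least 11.7-fold higher, since its probe was not above background on any Ad-Control array. Tceal5, Wfdc3 and the glutathione peroxidase gene Gpx2 had the same limit and were at least 4.63-fold, 4.53-fold and 3.93-fold higher. Without Ad-MafG 3 these bounds were 9.03-fold for Gstm3, 3.27-fold for Tceal5, 3.02-fold for Wfdc3 and 2.34-fold for Gpx2. Among named genes whose folds are not bounds, A2ml1 followed Cbr3 and Spink1 at 7.58-fold. Then came the antimicrobial peptide gene Defb1 at 6.73-fold, the protease inhibitor gene Slpi at 6.71-fold and Esco2, which acts in sister chromatid cohesion, at 6.27-fold. Defb1 and Esco2 were detected on 2 of the 3 Ad-Control arrays. With no background correction the log2 fold change was 4.29 for Cbr3 in place of 5.13, 3.21 for Spink1, 1.47 for both Defb1 and Esco2, 2.27 for Gstm3, 1.45 for both Tceal5 and Wfdc3 and 1.38 for Gpx2, so the bounds hold only with background removed. Among named genes past the threshold, the largest falls were in the serum amyloid genes Saa1, 4.75-fold lower, and Saa2, 3.99-fold lower. Hsd3b5 had a lower log2 fold change of -2.98 but did not pass (adjusted p = 0.0516), though it passed in 5 of 17 alternatives, and its value was -3.72 without Ad-Control 1, -2.32 without Ad-Control 2, -2.39 without Ad-MafG 3 and -2.07 with no background correction. Among probes without a listed gene, 1 had -2.50 (adjusted p = 0.0421). Masp1, a protease of the lectin complement pathway, was 3.57-fold lower, with a log2 fold change of -1.84 and an SE of 0.24. Rgs16 was 2.88-fold lower and the epidermal growth factor receptor gene Egfr 2.70-fold lower. Macrod1, Susd4, Ces3b, Sntg2 and Sugct were between 2.60-fold and 2.68-fold lower, and with no background correction Susd4 had a log2 fold change of -0.68 and Sntg2 one of -0.56. The adjusted p of these 20 genes ran from 0.00524 to 0.0475. With each array left out in turn, 11 of the 20 passed in all 6 fits. The exceptions were Wfdc3, which reached 0.0511 without Ad-Control 3, Gpx2, which missed without Ad-Control 1, Ad-Control 3 or Ad-MafG 1 (up to 0.0785), Saa2 without Ad-Control 1 or 3 (0.0733), Sugct without Ad-Control 3 (0.0564) and Susd4 without Ad-Control 3 or Ad-MafG 2 (0.069). Rgs16 missed without Ad-Control 3 or any 1 Ad-MafG array (up to 0.0863), Macrod1 without any 1 array but Ad-Control 2 (0.0822), Egfr without any but Ad-Control 1 (0.128) and Sntg2 without any but Ad-MafG 1 (0.111). With all 6 arrays, Egfr and Sntg2 also missed with the authors' scaled values, with no detection filter and with array weights, and Egfr with trend and robust eBayes, at an adjusted p of up to 0.0771 for Egfr and 0.0654 for Sntg2. Saa1 and Saa2 are close in sequence, as are the glutathione transferases of 1 class, and their separate values are uncertain.

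At least 2-fold differences were 198 higher and 42 lower among the changed genes. In 36.2% of the genes tested the 3 Ad-MafG values all lay on 1 side of the 3 Ad-Control values, against 10% by chance. All 875 changed genes had the same sign in the difference score of the authors' deposited table. That score compares the same arrays, so the shared sign is not independent support. The count of changed genes was 338 without Ad-Control 1, 238 without Ad-Control 3, 191 without Ad-MafG 1, 374 without Ad-MafG 2 and 211 without Ad-MafG 3. Of the changed genes 63.4% were higher, and with median scaling in place of quantile normalization 49.8% were, as 583 genes higher and 587 lower.

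Genes of the antioxidant response that NRF2 activates rose as a group in the livers labelled Ad-MafG. Of 24 such genes tested, 14 rose, 0 fell and 10 did not pass the test, with 16 higher when adjusted over the list alone. Besides Cbr3, Gstm3 and Gpx2, Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, rose 2.74-fold (log2 fold change 1.46, SE 0.21, adjusted p = 0.0123). Gstm2 rose 2.47-fold (adjusted p = 0.0111). Outside the rule for naming genes and chosen after its values were seen, the quinone reductase gene Nqo1 had a log2 fold change of 2.23 and an SE of 0.38 (adjusted p = 0.0199). The log2 fold change of Gclm was 0.36 and that of Txnrd1 0.21, and neither passed the test. NRF2 targets had a median log2 fold change of 0.92, also with Gstm3 and Gpx2 at their bounds. The camera adjusted p was 5.03e-11, and the adjusted p was 0.448 with an estimated correlation. Of the 14 calls, 6 were made without Ad-Control 1, 8 without Ad-Control 3, 5 without Ad-MafG 1, 13 without Ad-MafG 2 and 10 without Ad-MafG 3. Among the 5 tested genes of the list of MafG partners and relatives, which also holds Keap1, 0 passed limma's threshold. Of these genes 2 had an unadjusted p under 0.05. Nfe2l2, which encodes NRF2, had a log2 fold change of 0.47 (adjusted p = 0.146) and Bach1 one of -0.56 (adjusted p = 0.0832).

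**Figure D1:**
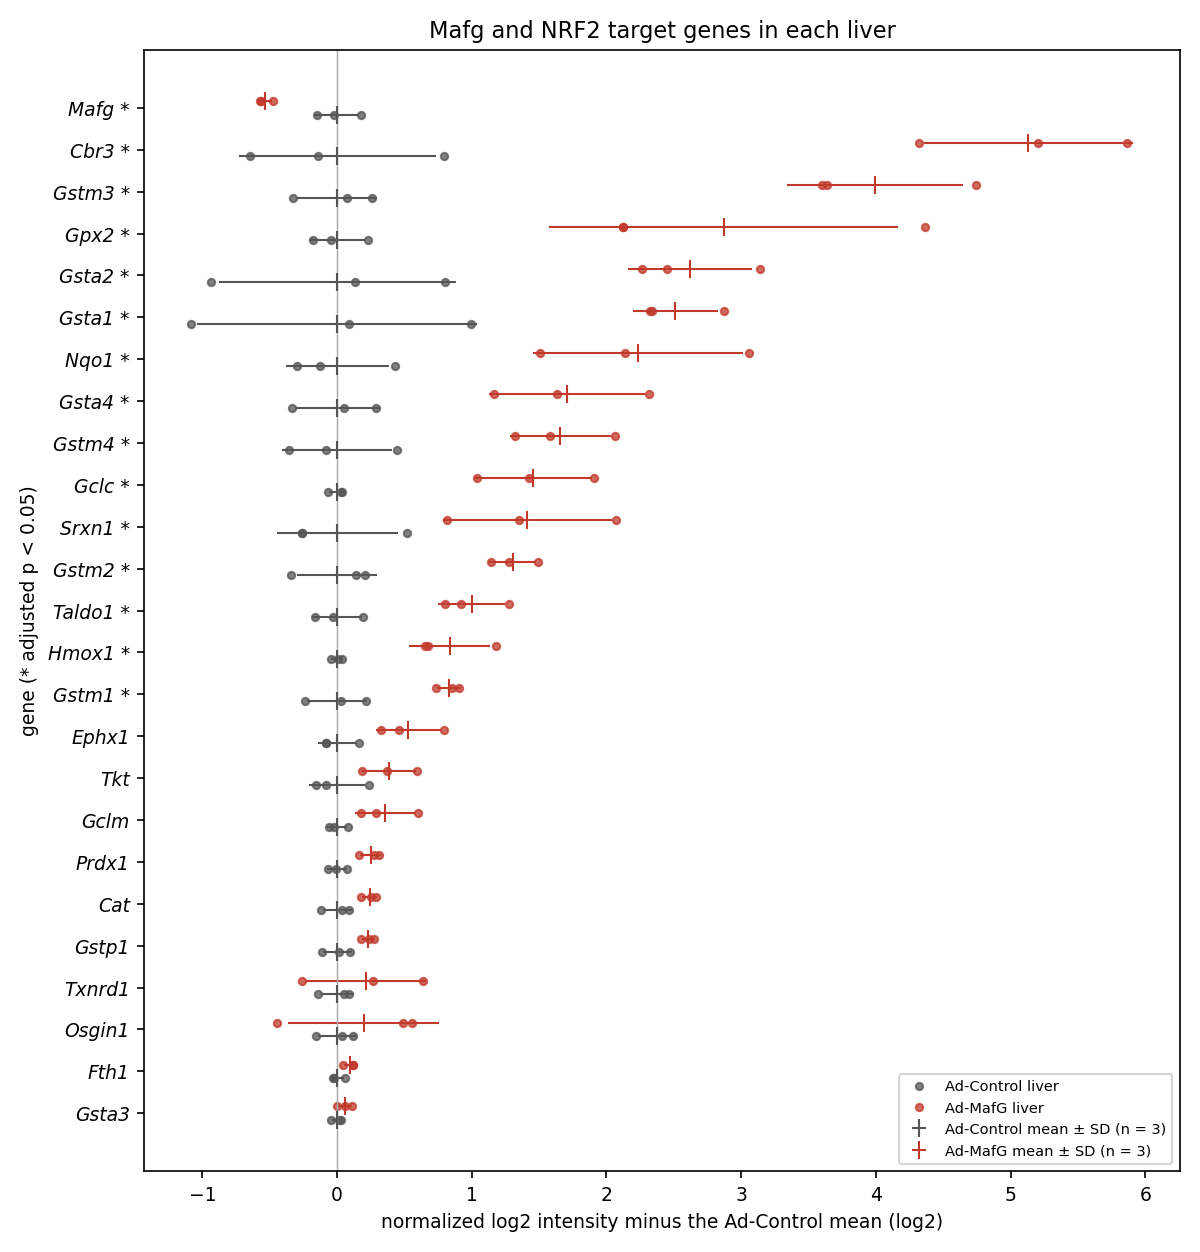
Normalized log2 intensity minus the Ad-Control mean (log2, horizontal axis) of Mafg and the 24 tested NRF2 target genes (vertical axis), with 1 point per liver and the mean ± SD of each group of 3 as a tick and line. Grey is Ad-Control and red Ad-MafG, stars mark an adjusted p under 0.05, Gstm3 and Gpx2 were not above background in Ad-Control, and Mafg lies at -0.54 while Cbr3 lies at 5.13.

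Bile acid synthesis genes did not move in 1 direction as a group in the livers labelled Ad-MafG. Of 16 tested, Acox2, a peroxisomal oxidase of the bile acid side chain, rose and Slc27a5, the bile acid CoA ligase, fell, while 14 did not pass the test. Acox2 had a log2 fold change of 0.49 with an SE of 0.10 (adjusted p = 0.0341), and Slc27a5 one of -0.71 with an SE of 0.13 (adjusted p = 0.025). The same 1 higher and 1 lower were counted when adjusted over the list alone. By limma 6 of the 16 had an unadjusted p under 0.05, against 2631 of all 8827 genes. For Cyp7a1, the rate-limiting enzyme of the classical pathway, the log2 fold change was -0.04 with an SE of 0.25 (adjusted p = 0.93). Cyp8b1, the sterol 12-alpha-hydroxylase required for cholic acid, had 14.63 ± 0.10 in Ad-Control and 13.91 ± 0.51 in Ad-MafG (SD, n = 3 each). Its log2 fold change of -0.72 had an SE of 0.24, and the 3 Ad-MafG values lay below the 3 Ad-Control values, but the adjusted p was 0.0969. Cyp8b1 passed with median scaling (adjusted p = 0.0436) and without Ad-MafG 2 (adjusted p = 0.0457). Cyp7b1 had a log2 fold change of -1.01 with an SE of 0.42 (adjusted p = 0.157), and Cyp27a1 had -0.25 with an SE of 0.12 (adjusted p = 0.222). The remaining 10 genes, Abcd3, Akr1d1, Amacr, Baat, Cyp2c70, Cyp39a1, Hsd17b4, Hsd3b7, Scp2 and Slc27a2, had values from -0.34 to 0.35 and did not pass the test. The list's median log2 fold change was -0.05 (camera adjusted p = 0.612; adjusted p = 0.844 with an estimated correlation). With median scaling the median was -0.34 and the camera adjusted p was 0.0478, against 0.0478 to 0.844 over all alternatives. Neither Acox2 nor Slc27a5 passed without Ad-Control 1, Ad-Control 3 or any of the 3 Ad-MafG arrays, where the highest adjusted p was 0.1 for Acox2 and 0.0854 for Slc27a5. Acox2 also missed the threshold with median scaling (log2 fold change 0.24, adjusted p = 0.188) and with the authors' scaled values (0.35, adjusted p = 0.07).

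Among 12 genes of bile acid and bile lipid transport, Slc10a1, the main hepatocyte importer of conjugated bile acids, was the only one past the threshold. It fell, with a log2 fold change of -0.69 and an SE of 0.16 (adjusted p = 0.0437). Slc51b, a subunit of the basolateral exporter, had a log2 fold change of 1.30 with an SE of 0.33 (adjusted p = 0.0516) and passed in 7 of 17 alternatives, 6 of them with all 6 arrays, with an adjusted p down to 0.0339 and a log2 fold change from 0.67 to 1.63. Adjusted over the list alone, 1 gene was higher and 1 lower, namely Slc51b and Slc10a1. By limma 6 of the 12 had an unadjusted p under 0.05, against 2631 of all 8827 genes. The canalicular export pump gene Abcb11 had a log2 fold change of 0.05 with an SE of 0.13, and the phospholipid floppase gene Abcb4 one of 0.05 with an SE of 0.11. Abcc2, Abcc3, Abcg5, Abcg8, Atp8b1, Slco1a4, Slco1b2 and Slco2b1 had values from -0.42 to 0.34, none past the threshold, though with median scaling Slco1b2 and Slco2b1 passed (adjusted p = 0.0483 and 0.0406), as did Slco2b1 with trend and robust eBayes (0.0375). The list's median log2 fold change was -0.02 and the camera test pointed down, while its mean was 0.005 (camera adjusted p = 0.779; adjusted p = 0.844 with an estimated correlation). Slc10a1 did not pass without Ad-Control 1, Ad-Control 3 or any of the 3 Ad-MafG arrays, with an adjusted p of up to 0.135, nor with the authors' scaled values (0.0562) or with no detection filter (0.0646). Its signal was low, with an authors' mean intensity of 213 in Ad-Control and 133.8 in Ad-MafG. Slco1b2 had 9026.4 and 6751.7, and Slc51b 71 and 203.3.

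**Figure D2:**
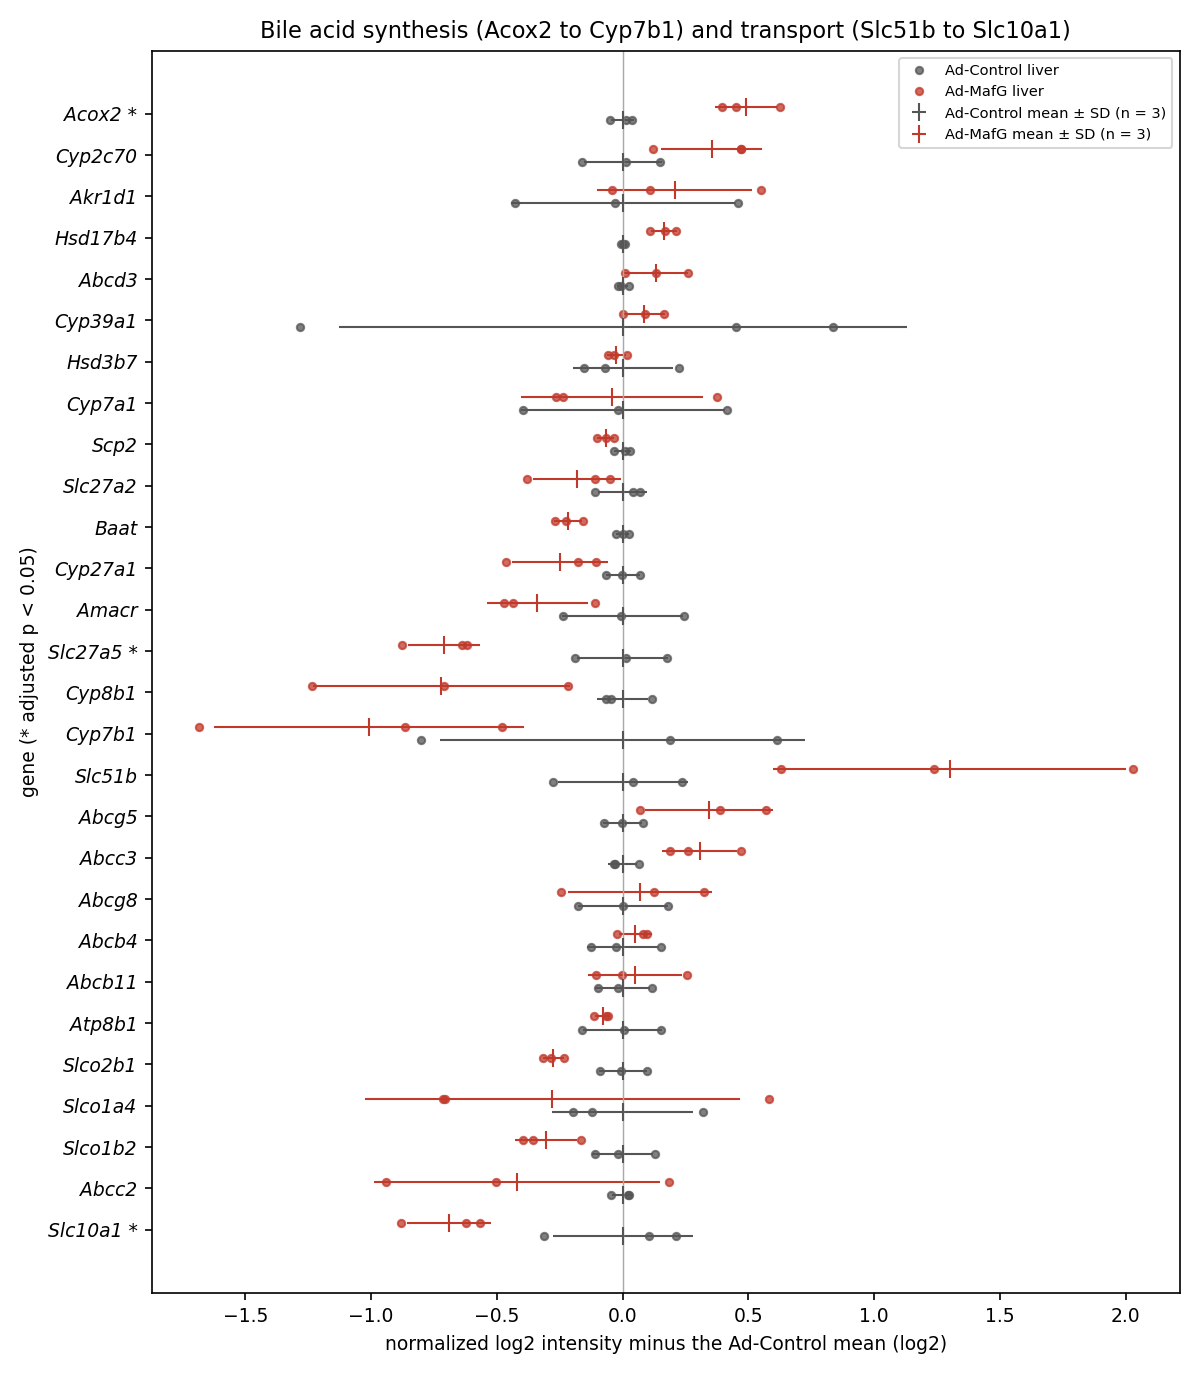
Normalized log2 intensity minus the Ad-Control mean (log2, horizontal axis) of the 16 bile acid synthesis genes, Acox2 to Cyp7b1, and the 12 transport genes, Slc51b to Slc10a1 (vertical axis), with 1 point per liver and the mean ± SD of each group of 3 as a tick and line. Grey is Ad-Control, red is Ad-MafG and stars mark the 3 genes with an adjusted p under 0.05, Acox2 at 0.49, Slc27a5 at -0.71 and Slc10a1 at -0.69.

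Nuclear receptors and regulators of bile acid metabolism lay lower as a group, with 11 of 12 members below 0. Nr1i3, the xenobiotic receptor CAR, fell from 11.91 ± 0.12 to 11.07 ± 0.02 (SD, n = 3 each), a log2 fold change of -0.83 with an SE of 0.10 (adjusted p = 0.00999). Rxra, the shared dimer partner of these receptors, fell by 0.45 on the log2 scale (adjusted p = 0.0444). Adjusted over the list alone, 6 were lower. The bile acid receptor gene Nr1h4 had a log2 fold change of -0.38 (adjusted p = 0.0621) and the FGF co-receptor gene Klb one of -0.56 (adjusted p = 0.0603); Nr1h4 passed in 5 of 18 alternatives and Klb in 4. The list's median was -0.42 (camera adjusted p = 0.00199; adjusted p = 0.357 with an estimated correlation). Rxra did not pass with any 1 array left out, with an adjusted p of up to 0.133, nor with cyclic loess (0.0548), the authors' scaled values (0.0745) or no detection filter (0.0557). Hepatocyte markers moved alongside, with 8 of 8 below 0, a median of -0.22 and a camera adjusted p of 0.0936. The hepatocyte marker list passed the camera test under 5 alternatives, with an adjusted p down to 0.00323 and a median down to -0.47.

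Cell cycle and DNA replication genes rose in the livers labelled Ad-MafG. Of 20 tested, 10 rose, 0 fell and 10 did not pass the test, with 13 higher when adjusted over the list alone. The mitotic kinase genes Cdk1 and Plk1 rose 3.89-fold and 2.44-fold (adjusted p = 0.011 and 0.0111). Aurka, detected on 1 of the 3 Ad-Control arrays, rose by 1.94 on the log2 scale with an SE of 0.25, and Birc5 rose 2.59-fold. With no background correction the log2 fold change of Cdk1 was 1.36 in place of 1.96 and that of Aurka 0.85. Cell cycle genes had a median log2 fold change of 1.04 (camera adjusted p = 2.24e-09; adjusted p = 0.45 with an estimated correlation). Calls on its members numbered 8 without Ad-Control 1, 8 without Ad-Control 3, 7 without Ad-MafG 1, 8 without Ad-MafG 2 and 8 without Ad-MafG 3. Of 12 p53 targets and DNA damage genes, 3 rose and 0 fell, with 5 higher when adjusted over the list alone. These were Phlda3, detected on 1 of the 3 Ad-Control arrays and 3.53-fold higher, Polk at 1.54-fold and Ccng1 at 1.70-fold. Their list had a median of 0.31 (camera adjusted p = 0.00517; adjusted p = 0.448 with an estimated correlation). Of these 3, 0 passed without Ad-MafG 3, 1 without Ad-MafG 1 and 2 without Ad-Control 1, Ad-Control 3 or Ad-MafG 2. Ccng1 missed with no detection filter (adjusted p = 0.056), and Phlda3 had a log2 fold change of 0.81 in place of 1.82 with no background correction.

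Markers of macrophages and of stellate cells lay higher as groups in the same livers. Of 11 Kupffer cell and macrophage markers tested, 6 rose and 0 fell. Adgre1, which encodes the macrophage surface protein F4/80, rose 2.64-fold (log2 fold change 1.40, SE 0.17, adjusted p = 0.00993). The complement genes C1qc and C1qb rose 2.19-fold and 1.98-fold, and Cd14, a receptor for lipopolysaccharide, rose 2.56-fold. Adjusted over the list alone, 6 were higher and 1, Marco, lower. Of the 5 members that did not pass over all genes, 4 chosen after their values were seen had log2 fold changes of -1.06 for Marco (adjusted p = 0.101), -1.48 for Timd4 (adjusted p = 0.249), 0.27 for Clec4f (adjusted p = 0.355) and 0.24 for Vsig4 (adjusted p = 0.462). Over the 11 markers the median was 0.77 (camera adjusted p = 0.00199; adjusted p = 0.448 with an estimated correlation). Of the 6 calls, 4 were made without Ad-Control 1, Ad-Control 3 or Ad-MafG 1, 3 without Ad-MafG 2 and 2 without Ad-MafG 3. Of 12 stellate cell and fibroblast markers, 4 rose and 0 fell, also when adjusted over the list alone. Col1a2, not above background in Ad-Control, was at least 1.61-fold higher, Col1a1 was 2.79-fold and Lum 1.76-fold higher, and Col3a1 had a log2 fold change of 0.998. Of the 8 stellate markers that did not pass, Timp1 had 0.96, Acta2 0.61, and Lrat, Pdgfrb and Dcn 0.17 to 0.31. Des, Reln and Rgs5 had -0.13 to -0.02. With no background correction the log2 fold change was 0.77 for Col1a1 in place of 1.48 and 0.50 for Col1a2, and with no detection filter Lum missed the threshold (adjusted p = 0.0592). That list had a median of 0.46 (camera adjusted p = 0.00517; adjusted p = 0.357 with an estimated correlation). The camera adjusted p of the stellate list was 0.125 with detection required on all 6 arrays. Of the 4 stellate calls, 1 was made without Ad-Control 1, Ad-Control 3 or Ad-MafG 2, 2 without Ad-MafG 1 or Ad-MafG 3 and 3 without Ad-Control 2.

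The other cell type lists did not pass the camera test. In the T and NK cell list 0 of 11 genes passed limma's threshold, with 2 at an unadjusted p under 0.05 and a median of 0.28 (camera adjusted p = 0.612), though without Ad-Control 2 the median was 0.64 and the camera adjusted p 0.0161. In the liver sinusoidal endothelial list 0 of 10 passed, with 1 at an unadjusted p under 0.05 and a median of 0.08 (camera adjusted p = 0.612); Lyve1 had a log2 fold change of 1.05 (adjusted p = 0.0542) and passed in 4 of 18 alternatives. In the neutrophil list 0 of 4 passed, with 1 at an unadjusted p under 0.05 and a median of 0.13 (camera adjusted p = 0.559). The B and plasma cell list had 0 of 2 past, 0 at an unadjusted p under 0.05 and a median of -0.10 (camera adjusted p = 0.693), and the cholangiocyte list 0 of 3, also 0 unadjusted, and -0.16 (camera adjusted p = 0.612). Of 2 erythroid genes, Alas2, the erythroid enzyme of heme synthesis, fell 2.19-fold. The other, Hba-a1, had a log2 fold change of 0.40 (limma adjusted p = 0.217), and the list's camera adjusted p was 0.619. Alas2 did not pass without Ad-Control 1, Ad-MafG 1 or Ad-MafG 3, with an adjusted p of up to 0.0694. Of 8 hepatocyte markers 0 passed, with 2 at an unadjusted p under 0.05.

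Gluconeogenesis and glycogen genes lay lower, with 10 of 10 members below 0. Gys2, the liver glycogen synthase, fell from 11.31 ± 0.22 to 10.24 ± 0.14 (SD, n = 3 each), 2.11-fold lower with an adjusted p of 0.0111. Pck1, a key enzyme of gluconeogenesis, was 1.81-fold lower (adjusted p = 0.0375). Adjusted over the list alone, 6 were lower. Over the list the median was -0.59 (camera adjusted p = 0.00199; adjusted p = 0.52 with an estimated correlation). Pck1 did not pass without Ad-Control 1, Ad-Control 3, Ad-MafG 1 or Ad-MafG 3, with an adjusted p of up to 0.108, nor with no detection filter (0.0586), and fry's directional test of the list gave an adjusted p of 0.0627. Hepatocyte markers moved alongside these genes too, with 8 of 8 below 0 and a median of -0.22.

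Of 13 circadian clock genes 3 fell and 0 rose, with 7 lower when adjusted over the list alone. Nr1d1, the repressor REV-ERB alpha, was 1.70-fold lower (log2 fold change -0.77, SE 0.11, adjusted p = 0.0121). Its signal was low, with an authors' mean intensity of 95.5 in Ad-Control and 49.7 in Ad-MafG. Over the 17 alternatives that tested Nr1d1, its log2 fold change ran from -0.95 to -0.30. It was not tested with detection required on all 6 arrays. Per2 and Tef were 1.44-fold and 1.53-fold lower. Clock genes had a median of -0.53 (camera adjusted p = 0.0024; adjusted p = 0.357 with an estimated correlation). Of these 3 calls, 0 were made without Ad-MafG 1, 1 without Ad-Control 1, Ad-Control 3 or Ad-MafG 3 and 2 without Ad-Control 2 or Ad-MafG 2. Tef also missed with the authors' scaled values (adjusted p = 0.0603) and with no detection filter (adjusted p = 0.064).

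Among acute phase genes Saa1 and Saa2 fell, as did Apcs, 1.48-fold, and Itih4, 1.40-fold. Of 19 tested 4 fell, 0 rose and 15 did not pass the test, 5 of the 19 lying above 0, with 6 lower when adjusted over the list alone and a median of -0.23 (camera adjusted p = 0.00517; adjusted p = 0.448 with an estimated correlation). Of the 4 calls, 1 was made without Ad-Control 1 or Ad-Control 3, 3 without Ad-Control 2 and 2 without any 1 Ad-MafG array. Itih4 also missed with no detection filter (adjusted p = 0.061) and with array weights (adjusted p = 0.053). Among 20 genes of the type I interferon response, Irf7 and Mx2 fell 1.74-fold and 1.81-fold while Oas2 rose 1.55-fold, the same counts as when adjusted over the list alone. That list had a median of -0.34 (camera adjusted p = 0.0275; adjusted p = 0.844 with an estimated correlation). The interferon list's median was -0.07 without Ad-Control 2 (camera adjusted p = 0.604) and -0.34 without Ad-MafG 2 (camera adjusted p = 0.0774), and its camera adjusted p was 0.0912 with array weights; fry's directional test gave an adjusted p of 0.36. All 3 of its member calls were lost without Ad-Control 3 or any 1 Ad-MafG array and with no detection filter, where the adjusted p was 0.0714 for Irf7, 0.0578 for Mx2 and 0.0589 for Oas2. Irf7 and Mx2 also missed with the authors' scaled values, and Irf7 with cyclic loess and with array weights.

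Other lists did not pass the camera test. Cholesterol synthesis genes went both ways: Hmgcs1, Mvd and Nsdhl rose 1.74-fold, 1.99-fold and 1.36-fold while their activator Srebf2 was 1.58-fold lower, and the list of 18 had a median of 0.10 (camera adjusted p = 0.612). In fatty acid and triglyceride synthesis, Me1, the malic enzyme that supplies NADPH, rose 1.94-fold and Acaca 1.77-fold while the pyruvate kinase gene Pklr was 1.96-fold lower, with a median of -0.04 over 19 genes (camera adjusted p = 0.772). In heme synthesis and iron handling, Blvrb and the iron exporter gene Slc40a1 rose 1.63-fold and 1.53-fold, with a median of 0.01 over 14 genes (camera adjusted p = 0.612; fry adjusted p = 0.0239). The urea cycle gene Otc was the 1 hepatocyte secretory and identity gene of 17 to fall, by 1.97-fold, and that list's median was -0.12 (camera adjusted p = 0.0677, and down to 0.000711 in the 8 alternatives in which it passed). Cyp2d10 fell 1.48-fold among 17 xenobiotic cytochromes P450, a list with a median of -0.11, a mean of 0.15 and a camera test that pointed down (adjusted p = 0.619). Susd4 was the 1 of 10 male-biased genes past the threshold, and Hsd3b5 had a log2 fold change of -2.98 with an SE of 0.76 (adjusted p = 0.0516); the list's median was -0.27 (camera adjusted p = 0.134, and past the threshold with no detection filter and without Ad-Control 1). Ciita, the class II transactivator, rose 2.18-fold in the interferon gamma list, which had a median of 0.01 over 17 genes (camera adjusted p = 0.619), and Ddit3 rose 1.44-fold among 19 unfolded protein response genes, a list with a median of -0.08 (camera adjusted p = 0.693). Limma called 0 of 15 genes of fatty acid oxidation, with 5 at an unadjusted p under 0.05 and a median of 0.05 (camera adjusted p = 0.619). It called 0 of 12 immediate early and heat shock genes, with 3 at an unadjusted p under 0.05 and a median of 0.12 (camera adjusted p = 0.474). It called 0 of 4 female-biased genes, with 0 at an unadjusted p under 0.05; their median was -0.12 and their mean 0.19, with the camera test pointing down (adjusted p = 0.753). The list of MafG partners and relatives had a median of -0.10, which is the value of Keap1 (camera adjusted p = 0.619). With each array left out in turn, Me1 passed in all 6 fits, and the other called genes of these lists missed the threshold in at least 1 fit, each of the 6 arrays being the one left out for some of them, with an adjusted p of up to 0.129 for Nsdhl. With all 6 arrays, Mvd, Nsdhl, Ciita and Slc40a1 missed with no detection filter, Hmgcs1 and Slc40a1 with median scaling, and Hmgcs1, Blvrb and Slc40a1 with the authors' scaled values, at an adjusted p of up to 0.236 for Slc40a1.

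**Figure D3:**
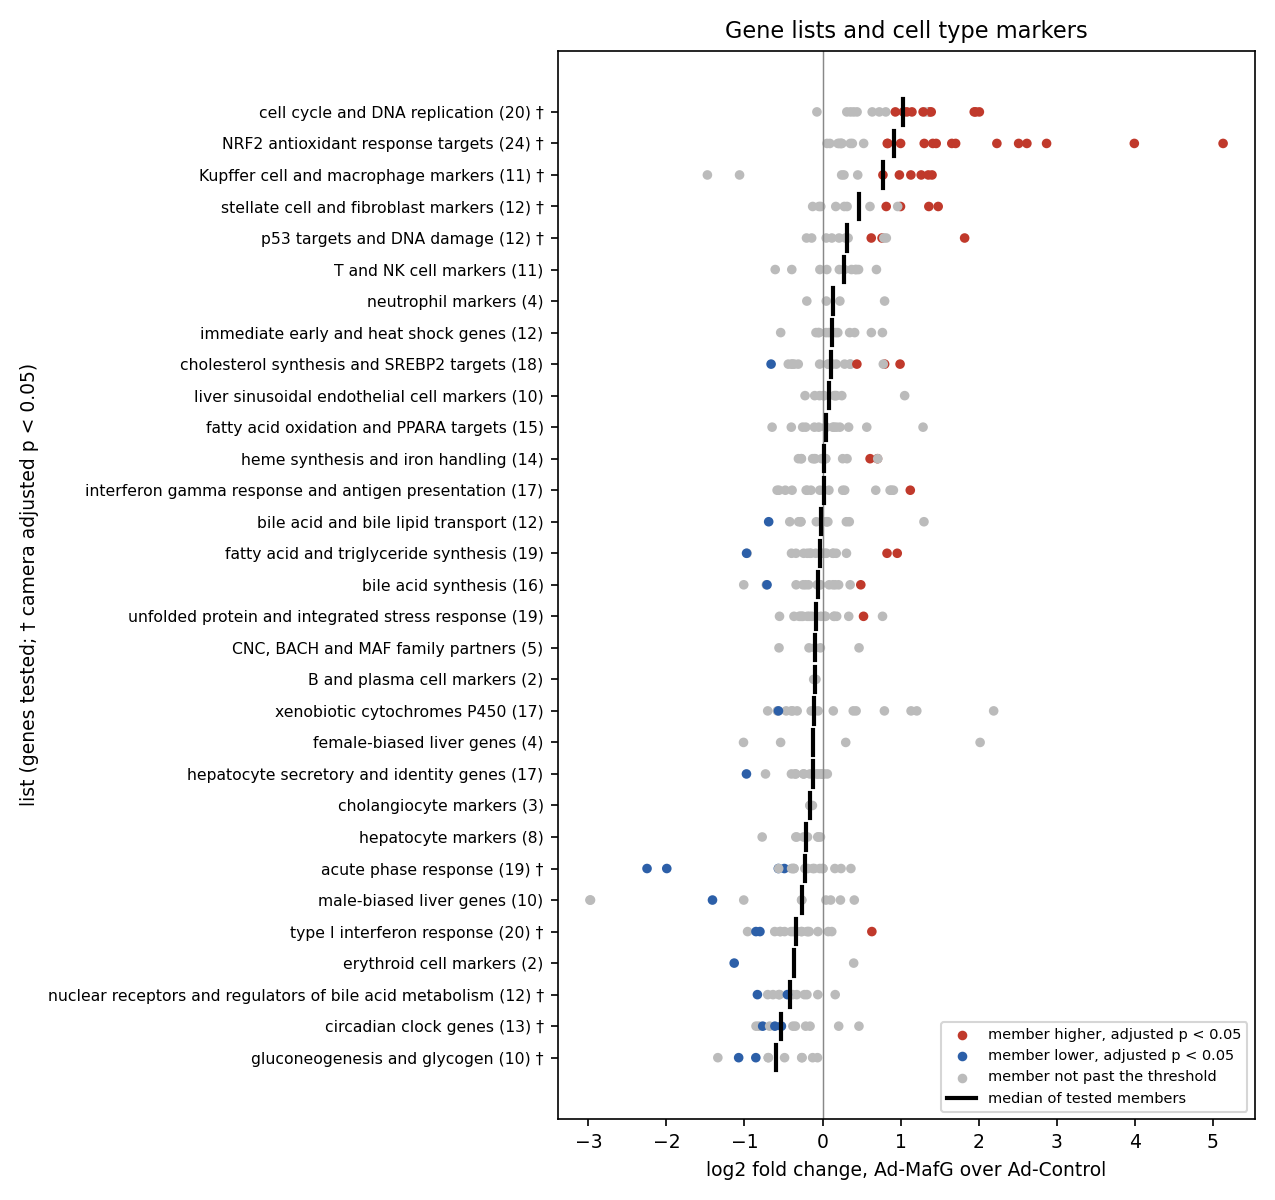
Log2 fold change, Ad-MafG over Ad-Control (horizontal axis), of the tested members of 31 gene lists and cell type marker lists (vertical axis, with the number tested). Points are genes, red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise, black bars are list medians, and daggers mark the 10 lists with a camera adjusted p under 0.05, whose medians run from -0.59 to 1.04.

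Of the 31 lists, 10 passed the camera test with its preset correlation, 9 passed fry's directional test, which asks whether a list's genes move 1 way on balance, and 0 passed camera with an estimated correlation after adjustment. The unadjusted p with an estimated correlation was under 0.05 for 3 lists, the nuclear receptors, the clock genes and the stellate cell markers. The direction of none of the 10 lists changed under another background correction, offset, scaling or source of the values. All 10 were measured in livers in which the median log2 fold change was 0.77 for macrophage markers, 0.46 for stellate cell markers and -0.22 for hepatocyte markers.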

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

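All tests of explanations in this part were chosen after the results were seen, except the count over splits of the samples. Probes without a listed gene lay outside every comparison, and among 748 of them that passed the detection filter 58 were higher and 26 lower in Ad-MafG livers than in the Ad-Control livers (limma, adjusted over 12893 probes). Their genes were not analysed here. For the count of 875 changed genes, the 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with as many genes, and the highest of the others gave 1.

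The lower Mafg probe signal runs against the overexpression named in the series title. Scaling or background correction is argued against: over 5 other settings the log2 fold change was at most -0.50, with an SE of 0.09. A swap of 1 sample between the groups is argued against too, since each array's mean correlation with its own group exceeded that with the other group, by at least 0.00638. An exchange of the groups as a whole stays open and was not tested. It also stays open that the probe reads only the mouse's own Mafg transcript and not that of the insert; the probe's position is not given in the sources used here.

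Cell cycle genes and macrophage markers were higher together. Brighter arrays in the Ad-MafG group are argued against as the whole cause, since the lowest median of the cell cycle list over 5 other background and scaling settings was 0.79 and its highest camera adjusted p was 9.08e-09, though with an estimated correlation the list's adjusted p was 0.45. A lower share of hepatocyte RNA would raise the markers of all other cell types alike, but mean changes were 0.57 (SE 0.13) for stellate cells, 0.49 (SE 0.17) for macrophages, 0.17 (SE 0.33) for T and NK cells, 0.15 (SE 0.12) for sinusoidal endothelium and -0.25 (SE 0.08) for hepatocytes. As the whole cause of the cell cycle rise it is argued against only where endothelium is the measure. The cell cycle rise exceeded the endothelial one by 0.86 with an SE of 0.30. Endothelium had the smallest mean rise of the cell types above. The cell cycle mean of 1.01 was not tested against the stellate cell or macrophage mean. The macrophage rise exceeded the endothelial one by only 0.34 with an SE of 0.18, less than 2 SE. By these means a lower hepatocyte share and a response to Ad-MafG cannot be told apart for the macrophage markers with 3 arrays per group. A lower share alone would move the markers of 1 cell type alike, and the means average members that moved both ways. Of 11 macrophage markers 9 lay above 0 and 2 below. Marco had -1.06 (limma adjusted p = 0.101) and Timd4 -1.48 (limma adjusted p = 0.249). Of 12 stellate markers 9 lay above 0 and 3 below.

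Clock genes were lower as a list (camera adjusted p = 0.0024; adjusted p = 0.357 with an estimated correlation), and time of harvest or feeding phase may differ between the groups. A shift in phase would move Arntl and Clock against the genes they drive. The mean change of Arntl and Clock, chosen after their values were seen, was 0.34 with an SE of 0.27, less than 2 SE from 0, with log2 fold changes of 0.47 (adjusted p = 0.37) and 0.21 (adjusted p = 0.358). Npas2 was not tested, and no time of harvest for each mouse is given in the sources used here. A phase difference and an effect of Ad-MafG on the clock genes cannot be told apart with 3 arrays per group.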

How the results depend on the processing

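Of the 875 changed genes, represented by 1 probe each, 0 changed sign under any alternative that tested them, nor did the 10 lists called, and all alternatives here were planned. Against 875 changed genes (555 higher, 320 lower), 1322 were called with no background correction (527 lower) and 1319 with trend and robust eBayes (528 lower). The lower count was 587 with median scaling, 212 with no detection filter, which tests 16593 genes, and 514 with every probe on its own. Leaving out 1 array gave 191 to 1170 changed genes, 153 to 736 higher and 38 to 434 lower: 338 without Ad-Control 1, 1170 without Ad-Control 2, 238 without Ad-Control 3, 191 without Ad-MafG 1, 374 without Ad-MafG 2 and 211 without Ad-MafG 3, with fewer samples in each fit. What equal replicate numbers mean is not given in the sources used here. Deviations from the group mean correlated at 0.043, -0.127 and -0.124 across genes for same-numbered samples, and 2 of 6 samples correlated best with their own number. With only 3 arrays per group centred on their own mean, these values cannot show whether the mice were paired. With the replicate block the counts were 141, 116 higher and 25 lower, and Mafg had -0.54 (adjusted p 0.0911). Mafg ranged from -0.62 to -0.45 with 1 array left out (adjusted p 0.028 to 0.109) and passed in 11 of the 12 other alternatives. Bile acid synthesis passed camera only with median scaling, at a median of -0.34 (adjusted p 0.0478); the cause was not tested. Its range with 1 array left out was -0.16 to -0.03, and that of transport, which passed under no alternative, -0.06 to -0.01. Of the 67 named genes called, 51 to 67 were called under each of the other 11 alternatives, 19 with the block and 30 to 57 with 1 array left out; 23 were called in all 6 of those fits. Detection on all 6 arrays left 122 of the 154 named genes and 51 of the 67. Values not called changed sign in at most 6 named genes per alternative. Of the 10 lists called, 9 or 10 were called under each alternative fit, 8 with fry and 0 with an estimated correlation. Of the lists not called, the hepatocyte identity list passed in 8 alternatives, hepatocyte markers in 5, male-biased genes in 2 and T and NK cells and heme in 1 each. The averaged table was not run, since it holds no value per sample. Dim probes limit the folds of Gstm3, Gpx2, Tceal5, Wfdc3 and Col1a2 to bounds.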

Other observations

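The tests of gene families in this part were chosen after the data were seen; the list of growth hormone targets was written before its values were looked at. Genes were grouped into families by the letters of their symbols, and 282 families with at least 5 tested members were examined for an excess of higher or lower genes with Fisher's one-sided exact test, 564 tests in all. In 3 families more genes rose than in the rest. Toll-like receptors, which sense microbial products, led with 6 of 8 higher (adjusted p = 0.000839): Tlr1, Tlr4, Tlr6, Tlr7, Tlr8 and Tlr13 had log2 fold changes from 0.76 to 1.52, and from 0.36 to 0.71 with no background correction. The macrophage markers moved with them, 6 of 11 higher at a median of 0.77, and several of these receptors are genes of myeloid cells. Of the mu class glutathione transferases 5 of 6 were higher (adjusted p = 0.00153), namely Gstm1, Gstm2, Gstm3, Gstm4 and Gstm6, similar transcripts whose separate values are uncertain. A dimmer Gstm6 probe had a log2 fold change of -0.01 with an SE of 0.16. With every probe on its own, dimmer probes of Gstm1 and Tlr13 had 0.30 (adjusted p = 0.213) and 0.51 (adjusted p = 0.103). The 2 further Gstm2 probes passed at 1.33 and 1.64. On the probe used, Gstm1 missed the threshold with median scaling (adjusted p = 0.0578) and with the authors' scaled values (adjusted p = 0.0582). Of the glutathione peroxidases 4 of 6 were higher (adjusted p = 0.039), Gpx2, Gpx3, Gpx4 and Gpx7. Gstm1, Gstm2, Gstm3, Gstm4 and Gpx2 are also among the 14 NRF2 targets called above, so these families in part repeat that result. On the probe used, all 15 genes of the 3 families were above 0 in each of 5 other background and scaling settings. Of the 6 Tlr calls 3 were made without Ad-MafG 1 or Ad-MafG 3, of the 5 Gstm calls 2 without Ad-MafG 1 and 3 without Ad-MafG 3, and of the 4 Gpx calls 2 without Ad-Control 1 or Ad-MafG 3 and 1 without Ad-Control 3 or Ad-MafG 1. Genes of a family are not independent, so these p-values are too small.

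A hypothesis is that growth hormone signalling was lower in the livers labelled Ad-MafG. It came from lower Egfr and Susd4 and from the log2 fold change of -2.98 of Hsd3b5 (adjusted p = 0.0516, and past the threshold in 5 of 17 alternatives), genes that growth hormone is known to maintain in male liver. Susd4 and Hsd3b5 were picked from the male-biased list after its values were seen, of which 4 of 10 genes lay above 0 and which did not pass camera (adjusted p = 0.134). A list of 10 other targets of growth hormone and STAT5B was then fixed, and 8 of them were tested. Their median log2 fold change was -0.49, with 7 of 8 below 0 and a camera p of 0.0062. The p was 0.149 with an estimated correlation, so the result rests on the preset one. By limma 0 of the 8 passed the adjusted threshold and 4 had an unadjusted p under 0.05. Socs2 had a log2 fold change of -0.99 (adjusted p = 0.057), Igf1 one of -0.73 (adjusted p = 0.072) and Ghr, the receptor, one of -0.38 (adjusted p = 0.0565). Since 8 of 8 hepatocyte markers also lay below 0, with a median of -0.22, a lower share of hepatocyte RNA or a wider decline of hepatocyte genes could give the same pattern and was not separated from it.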
